A study of Mus musculus with 4 samples.

How the data were processed

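The series covers 4 samples of mouse embryonic stem cells in which the endogenous CHD8 protein carries a FLAG tag: 2 anti-FLAG ChIP samples and 2 input samples without antibody. Replicate numbers were taken from the sample titles. Libraries were made by tagmentation on beads, per the labels' protocols. The aligner Bowtie2 2.1.0, the peak caller MACS2 2.1.1 and the build mm9 are named, without further detail, per the submitters' processing notes. Which control was used for which ChIP sample, and any further filter, are not given in the sources used here.

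Each ChIP sample came with 1 deposited peak list of 10 columns and no header; no table of the input samples was analysed here. The lists were made per sample, not on pooled samples. The deposited fold enrichment of a peak is the linear ratio of its summit over the caller's background. The deposited significance is given as −log10 of the p-value and −log10 of the q-value at the summit. The smallest −log10 q was 1.32 and 1.31, so every deposited q-value was under 0.05. The deposited score is 10 times the −log10 q-value cut to a whole number, which held for all peaks. The column of summit offsets was used to place summits. All fold enrichments and significances below are the authors'; they served to describe, rank or filter peaks within a list.

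The lists give no read numbers, but the fold enrichment and the p-value of a peak together fix them. For MACS2, fold is (s × n + 1)/(background + 1) and p is the Poisson tail beyond s × n, where n is the number of reads over the summit and s the factor that scales the ChIP library to a smaller control. The genome-wide background and s were read from the steps between the most frequent values, and each peak was then solved for a whole n and its local background. All peaks of both lists were solved with a misfit in log10 p under 0.002; in replicate 2, 78 peaks had more than one solution within that tolerance, and the closest was taken. The local backgrounds lay on a grid of whole control reads in windows of 200 bp, 1 kb and 10 kb, which gave the extension length of 200 bp. Control coverage below means this local background, from any of these windows around the summit. It has the genome-wide value as a floor, so a peak at that value may have had lower coverage. Per 200-bp window the ChIP libraries held 3.44 and 3.56 reads and the controls 3.54 and 2.55. With the caller's default mouse genome size, which the sources used here do not state, this would be 32.2 M and 33.3 M ChIP reads and 33.1 M and 23.8 M control reads. In replicate 2 the ChIP library was scaled by 0.714, and in replicate 1 the control was scaled by 0.970. The procedure was tested on simulated lists of the same lengths, 22706 and 31002 peaks, in which it recovered 100.0% and 99.99% of the read numbers. These lists were made with the same formulas, so they test the solving and not whether the formulas hold for the deposited lists. Their local backgrounds were the genome-wide value or whole numbers, simpler than the deposited ones.

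Overlap was counted from 1 bp. Connected overlapping peaks that hold a peak of both replicates formed a shared region, represented in each replicate by its peak with the highest −log10 q. Random placement used bedtools 2.31.1 (shuffle, within the chromosome, without overlap, 1000 seeds), within the span from the first to the last peak of each chromosome; densities per Mb use the same span. In a simulated copy of the replicate 1 list of 22706 peaks with 60% of its peaks kept, 60.0% were found again. Shares carry 95% Wilson intervals, densities and read numbers exact Poisson intervals, and the chromosome distribution was tested by Monte Carlo chi-square with 10000 draws. Calculations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and figures were drawn with matplotlib 3.10.9.

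The tests, the alternatives and 12 gene lists were fixed before the data were examined, except for the alternatives and tests named as added in the closing section. The rule for what is named took the 10 shared regions with the best rank, defined by the worse of a region's rank percentiles in the lists, and the 3 best peaks of each replicate without a partner. It also covered Chd8 and members of the gene lists, for use with an annotation of the same build. No annotation or sequence of mm9 was used here, and the gene table at hand is of GRCm38, so peaks are named by position alone. Promoter shares, gene lists and motifs were therefore not analysed, and no peak was assigned to a gene. The alternatives tried were the 50% of each list with the higher score, lists of equal length, 50% reciprocal overlap, autosomes only, each replicate alone, ranking by fold and leaving out peaks with high control coverage. A list of artefact-prone regions was not used here.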

Results

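CHD8, an ATP-dependent chromatin remodeller of the CHD family, was mapped by chromatin immunoprecipitation and sequencing in mouse embryonic stem cells grown in 2i medium, which holds such cells in a naive pluripotent state with inhibitors of MEK and GSK3. Both endogenous copies of the gene carried a C-terminal FLAG tag, and the protein was recovered with an antibody against the tag. The series held 2 ChIP samples and 2 input samples. No anti-FLAG ChIP of untagged cells was among them, so peaks that the antibody would give without tagged CHD8 cannot be told apart. CHD8 peaks, sites and regions below are those of the anti-FLAG ChIP. A peak list was analysed for each ChIP sample; the inputs entered only through the control background of the peak calls. The labels give 1 condition, so the comparisons were between the replicate ChIP samples and between parts of the genome. Nothing in the labels says that the replicates came from separate cultures, so agreement between them may be technical. The values recovered from the peak statistics gave 3.44 ChIP reads per 200-bp window in replicate 1 and 3.56 in replicate 2. The control tracks held 3.54 and 2.55 reads per window.

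CHD8 peaks were short and lay on every autosome and on the X chromosome in both replicates. Replicate 1 held 22706 peaks over 15.4 Mb and replicate 2 held 31002 peaks over 22.9 Mb, 1.37 times as many. The median peak was 495 bp wide in replicate 1 and 514 bp in replicate 2. Peaks wider than 1 kb made up 22.3% and 25.5% of the lists. The authors' fold enrichment had a median of 4.51 in replicate 1 (quartiles 3.67 and 6.15) and 4.71 in replicate 2 (quartiles 3.91 and 6.53), and reached 43.9 and 36.7. The median summit rested on 21 reads in replicate 1 and 24 in replicate 2, so that counting error alone was 21.8% and 20.4% of the value. The weakest peaks rested on 11 and 13 reads. The Poisson, Wilson and binomial intervals below cover counting error only.

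The same sites were found in both replicates far more often than placement by chance would give. Of the replicate 1 peaks, 20238 overlapped a replicate 2 peak by at least 1 bp, which is 89.1% (95% Wilson interval 88.7 to 89.5). Of the replicate 2 peaks, 18868 or 60.9% (60.3 to 61.4) overlapped a replicate 1 peak. When the replicate 2 peaks were placed at random within their chromosomes 1000 times, 387 ± 20.2 (SD over placements) replicate 1 peaks were met, 1.70% of the list. The observed number was 52.3 times the mean placed number, and no placement exceeded 457 (one-sided permutation p = 0.001, the smallest the placements can give). The placements did not keep the grouping of peaks described below or leave out sequence that reads cannot be aligned to. Both lower the placed number, so the excess is not a measure of agreement site by site. The overlapping peaks formed 17867 shared regions with a median width of 974 bp, and 84.3% of them held a single peak of each replicate. The summits of the replicates lay a median of 95 bp apart. Under the requirement of 50% reciprocal overlap, 59.5% of replicate 1 peaks were shared.

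Strong sites were shared almost without exception, and the lists differed at sites of middle and low strength. In the highest quintile of replicate 1 by −log10 q, 4541 of 4542 peaks had a partner in replicate 2. In the highest quintile of replicate 2, 6185 of 6201 peaks had a partner in replicate 1, which is 99.7% (99.6 to 99.8). In the middle quintile the shares were 92.5% in replicate 1 and 56.5% in replicate 2, where these peaks had a median fold enrichment of 4.71. In the lowest quintile the shares were 72.5% (71.1 to 73.7) in replicate 1 and 23.4% (22.4 to 24.5) in replicate 2. The 2468 peaks found only in replicate 1 had a median fold enrichment of 3.60 and a median width of 253 bp, against 4.73 and 565 bp for its shared peaks. The 12134 peaks found only in replicate 2 had medians of 3.91 and 304 bp, against 5.88 and 847 bp.

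**Figure D1:**
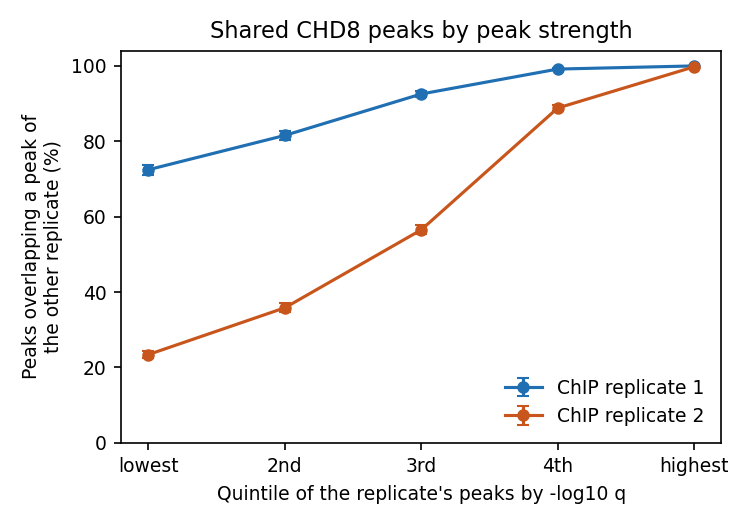
Percent of peaks that overlap a peak of the other replicate by at least 1 bp (y axis), by quintile of each replicate's own peaks ordered by −log10 q (x axis). Points are shares and bars are 95% Wilson intervals; the share rose from 72.5% to 99.98% in replicate 1 and from 23.4% to 99.7% in replicate 2.

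Regions that were strong in replicate 1 were also strong in replicate 2, and most regions had a higher level in replicate 2. Across the 17867 shared regions, Spearman's rho of the −log10 q values was 0.80, that of the fold enrichments 0.74 and that of the summit read numbers 0.84. These are correlations across regions, which are not independent replicates, and no p-value is given. After division by ChIP depth, the summit read number was higher in replicate 2 at 88.4% of the regions, with a median ratio of 1.25 (bootstrap 95% interval over regions 1.25 to 1.26). By quintile of strength, from weak to strong, the median ratio was 1.22, 1.29, 1.30, 1.29 and 1.19, and 84.5%, 88.2%, 90.3%, 90.1% and 88.9% of the regions were higher in replicate 2. At the 10 best-ranked regions the median ratio was 1.04, with ratios of 0.90 to 1.07 and 7 higher in replicate 2. Fold enrichment was lower in replicate 2 at 8 of these 10, but the folds of the lists are not on the same scale. The caller adds 1 to the scaled summit and to the background, which was 3.44 genome-wide in replicate 1 and 2.55 in replicate 2. At these backgrounds an equal depth-normalised summit gives a lower fold in replicate 2. On chromosome 4 at 21773918 to 21776287, 132 and 143 reads gave folds of 29.96 and 29.09. The log2 ratio had an SD of 0.29, below the 0.40 expected from independent counts of these sizes. Around the median ratio, an exact binomial test found 0 regions that differed at a Benjamini-Hochberg adjusted p under 0.05 and 232 at an unadjusted p under 0.05, 1.298% of the regions. Against the plain depth ratio, 1 region passed the adjusted threshold and 1113 the unadjusted one. These tests compare 2 libraries, and a summit is the highest point of a peak, so its reads are not a count at a fixed position. They also leave out the peaks found in 1 replicate alone. With a spread below the counting expectation, few regions could pass, so the tests do not show that the replicates are equal.

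**Figure D2:**
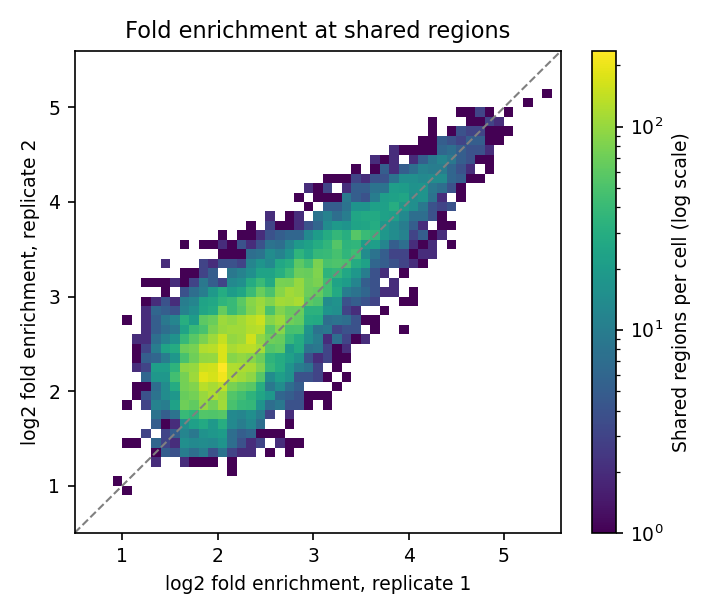
Number of shared regions (colour, log scale) by the authors' fold enrichment on the log2 scale in replicate 1 (x axis) and replicate 2 (y axis). The dashed line marks equal values; most regions lie above it, and the medians are 4.96 in replicate 1 and 5.96 in replicate 2.

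The strongest CHD8 sites were regions of 1442 to 2572 bp on 7 chromosomes, with mean fold enrichments of 28.0 to 40.3. They are the 10 shared regions with the best rank, taken as the worse of a region's rank percentiles in the lists. They are given by position in mm9, 1-based. The strongest was on chromosome 19 at 3766850 to 3769421. It ranked 1 in both lists, with a fold enrichment of 40.3 ± 5.08 (SD, n = 2) and summits of 194 and 181 reads that lay 103 bp apart. The next was on chromosome 12 at 44073336 to 44075091, with a fold enrichment of 34.8 ± 3.29 (SD, n = 2) and summits 62 bp apart. The region on chromosome 8 at 73396653 to 73398181 had 28.7 ± 2.63 (SD, n = 2) and summits 11 bp apart. The region on chromosome 1 at 63222376 to 63224611 had 31.8 ± 0.64 (SD, n = 2). Chromosome 4 held a pair of these regions, at 139814443 to 139815884 with 30.3 ± 4.37 (SD, n = 2) and at 21773918 to 21776287 with 29.5 ± 0.62 (SD, n = 2). The region on chromosome 12 at 72236905 to 72238741 had 29.3 ± 0.90 (SD, n = 2). Chromosome 9 also held a pair, at 21754256 to 21756090 with 28.0 ± 4.35 (SD, n = 2) and at 103964973 to 103966757 with 29.3 ± 0.30 (SD, n = 2). The region on chromosome 17 at 33128927 to 33131228 had 28.1 ± 2.57 (SD, n = 2). All 10 stood at rank 15 or better in replicate 1 and rank 18 or better in replicate 2, with summits of 130 to 194 reads. The exact Poisson interval of the chromosome 19 site was 38.0 to 50.5 in replicate 1 and 31.6 to 42.5 in replicate 2, and these intervals overlap. The lists differ in fold scale, as given above, and the SDs include that difference. At chromosome 8 the control background was 1.46 and 1.23 times the genome-wide value; at chromosomes 19 and 1 it was at the genome-wide value in both replicates.

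The best peaks without a partner were of moderate strength. In replicate 2 the first was on chromosome 9 at 114555644 to 114556607, with a fold enrichment of 9.14 (exact Poisson interval 6.72 to 12.2), and the nearest replicate 1 peak lay 5502 bp away. The second was on chromosome 8 at 113278556 to 113281022, 2467 bp wide, with 7.77 (5.75 to 10.3). The third was on chromosome 3 at 127155868 to 127156216, with 8.34 (6.04 to 11.3), 773 bp from a replicate 1 peak. In replicate 1 the first was on chromosome 6 at 84624155 to 84624570, with 6.76 (4.69 to 9.46), 38343 bp from the nearest replicate 2 peak. The second was on chromosome 2 at 139921768 to 139922118, with 6.76 (4.60 to 9.61). The third was also on chromosome 2, at 70395971 to 70396557, with 6.31 (4.23 to 9.07), and lay 157 bp from a replicate 2 peak. They ranked 4497, 4927 and 5732 in replicate 1 and 3559, 4476 and 4605 in replicate 2. Within 1 kb of a peak of the other replicate lay 39.1% of the peaks found only in replicate 1 and 27.1% of those found only in replicate 2.

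CHD8 regions were spread unevenly over the chromosomes, with the highest density on chromosome 11 and a low one on the X chromosome. Chromosome 11 held 12.02 shared regions per Mb (95% exact Poisson interval 11.4 to 12.7), followed by chromosome 19 with 10.1 (9.28 to 10.9), chromosome 17 with 9.35 (8.74 to 9.997) and chromosome 8 with 9.09 (8.58 to 9.63). Among the autosomes, chromosome 14 had the lowest density, 5.31 (4.90 to 5.74), and chromosome 1 had 5.43 (5.11 to 5.77). The X chromosome held 312 shared regions, 1.96 per Mb (1.74 to 2.19), against 7.31 per Mb over the 19 autosomes. The ratio of these densities was 0.27 (exact binomial interval 0.24 to 0.30), and it was 0.25 in each replicate's own list. The median fold enrichment was 4.96 at X regions and 4.96 at autosomal regions in replicate 1, and 5.67 against 5.96 in replicate 2. Control coverage was also lower at X peaks: it exceeded the genome-wide background at 3.98% of X peaks and 47.8% of autosomal peaks in replicate 1, and at 6.11% and 41.9% in replicate 2. X folds were thus mostly taken over the genome-wide background, and X and autosomal peaks passed the same calling threshold. The similar medians therefore do not show equal enrichment over the control. The Y chromosome held 6 peaks in replicate 1 and 4 in replicate 2. The share of peaks per chromosome differed between the lists by at most 0.24 percentage points (Monte Carlo chi-square p = 0.9993). The lists share most of their peaks, which lowers that statistic; between the peaks found in 1 replicate alone the p was 0.5654.

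**Figure D3:**
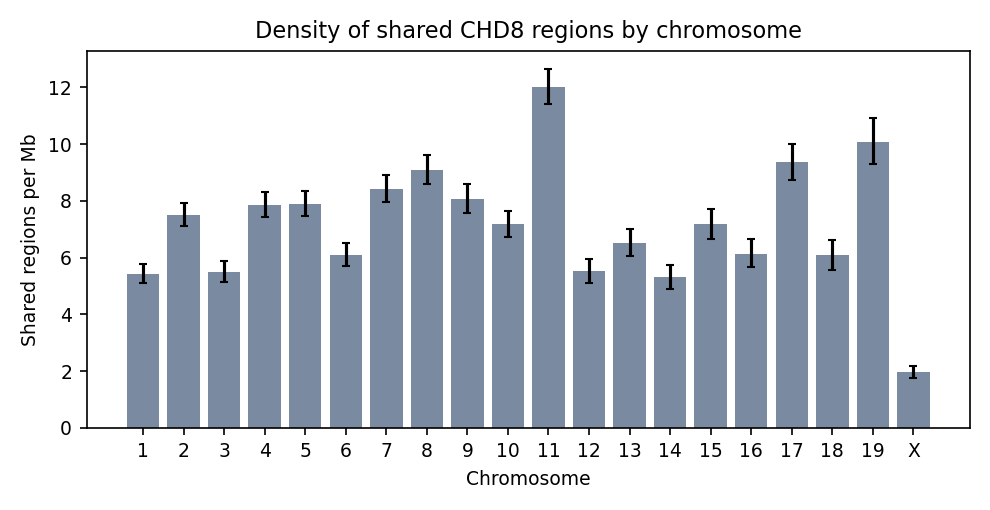
Shared regions per Mb (y axis) on each autosome and the X chromosome (x axis), over the span from the first to the last peak of the chromosome. Bars are densities and whiskers are 95% exact Poisson intervals; chromosome 11 reached 12.02 per Mb and the X chromosome 1.96.

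Within chromosomes the CHD8 regions lay in groups. The median gap between neighbouring shared regions was 33.6 kb, against 98.6 ± 0.78 kb (SD over placements) when the regions were placed at random, a ratio of 0.34 (one-sided permutation p = 0.001, the smallest the 1000 placements can give). A neighbour lay within 2 kb for 11.7% of the gaps against 1.39 ± 0.09% in the placements, and within 10 kb for 26.1% against 6.79 ± 0.18%. Of the 2540 full 1-Mb windows, 534 held no shared region, which is 21.0% against 0.09 ± 0.06% in the placements. Windows that made up 15.2% of the total held 50% of the regions. The number of peaks per window had a Spearman's rho of 0.97 between the replicates, across windows. The placements took no account of gaps in the assembly or of sequence that reads cannot be aligned to, where no peak can be called. They also took no account of enriched stretches that the caller may cut into several regions, which would shorten gaps.

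The densest window was on chromosome 13 from 23 to 24 Mb, with 64 shared regions, 84 replicate 1 peaks and 90 replicate 2 peaks. Some neighbours there lay close together, such as 23527466 to 23528125 and 23528175 to 23528528. Whether such neighbours are separate sites was not tested. The windows were singled out after their values were seen. The next were chromosome 7 from 52 to 53 Mb with 63 regions, chromosome 10 from 80 to 81 Mb with 55, chromosome 8 from 87 to 88 Mb with 54 and chromosome 11 from 97 to 98 Mb with 52. The mean window held 6.93 regions, and the fullest window in any of the 1000 placements held 23.

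**Figure D4:**
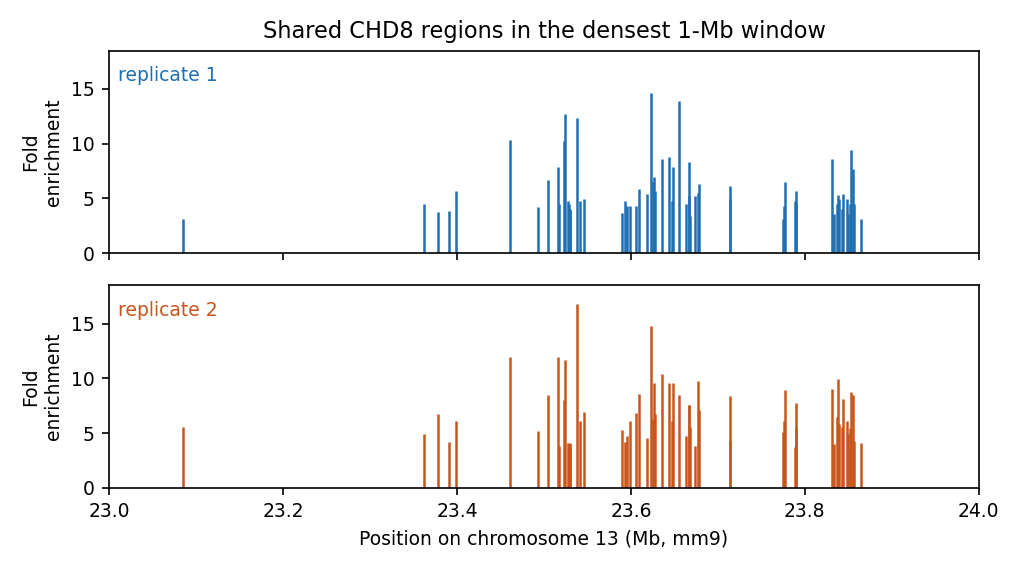
The authors' fold enrichment (y axis) of the 64 shared regions by position on chromosome 13 (x axis, Mb), with replicate 1 above and replicate 2 below. Each line is the best peak of that replicate in a region, drawn at the region's midpoint; the same positions carry the regions in both panels by construction, and the window held 84 and 90 peaks in all.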

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

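The tests of ChIP and control depth, of peak splitting and of recurring high-coverage loci, the correlation of control coverage, the ratios by strength, and the X comparisons at matched read numbers and with the 5th percentile were chosen after their values or related ones had been seen. The other tests of explanations in this section were written down first.

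Control coverage, which no column of the peak lists gives directly, is here the caller's local background over windows of 200 bp, 1 kb or 10 kb. It cannot fall below the genome-wide background, so peaks at that value may have had less. It exceeded the genome-wide background at 47.0% of replicate 1 peaks and 41.3% of replicate 2 peaks. Most of these excesses were small: coverage reached 2 times the background at 246 and 340 peaks and 4 times at 11 and 10 peaks. The tables argue against counting noise of the control as the source of the larger excesses, if the replicates have separate controls: 28 shared regions were at 2 times the background at the best peak of both replicates and independent draws would give 2.79. Which control served which replicate is not stated. The control tracks held 3.54 reads per 200-bp window in replicate 1 and 2.55 in replicate 2, which argues against the same control reads for both. Differently filtered copies of a single input stay open. The control coverage of the replicates had a Spearman correlation of 0.17 to 0.20 over the 4 summit distances tried, and no value for such copies was worked out. Values held at the genome-wide background are ties, which limits this correlation. Of the 11 replicate 1 peaks at 4 times the background, 7 or 63.6% met a replicate 2 peak at 2 times, as loci that gather reads in any library would. The other 4, among them the highest 3, remain open. Whether the small excesses go beyond counting noise of the control was not tested.

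The 3 replicate 1 peaks with the highest control coverage had no overlapping replicate 2 peak. That on chromosome 15 at 74917024 to 74917509 had 33.6 times the background, and a replicate 2 peak with 8.64 times lay 729 bp away. That on chromosome 17 at 39984830 to 39985126 had 23.7 times and its nearest replicate 2 peak, 646715 bp away, was at the background. That on chromosome 11 at 3093206 to 3093693 had 22.6 times, with a replicate 2 peak of 4.31 times 8241 bp away. Coverage in replicate 2 is known only where it has a peak. The overlapping peaks with the highest control coverage in both replicates lay in shared regions on chromosome 8 at 19982609 to 19983075, with control coverage of 11.8 and 11.8 times the background and fold enrichments of 1.89 and 2.13, and on chromosome 19 at 61275622 to 61275836, with 8.46 and 10.2 times and folds of 2.06 and 1.97. On chromosome 7 a replicate 1 peak at 7251167 to 7252515 had 6.21 times the background and an overlapping replicate 2 peak at 7252022 to 7252506 had 5.89 times. Those on chromosome 18 at 3005677 to 3006046, chromosome 4 at 146791282 to 146791642 and chromosome 11 at 3101935 to 3102457 had control coverage of 4.11 to 8.25 times the background. At the 10 strongest CHD8 regions the control was at most 1.46 times the background.

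Replicate 2 gave 1.37 times as many peaks. The tables argue against ChIP depth as the cause, since 30795 of the replicate 2 peaks kept their significance when scaled to the ChIP depth of replicate 1, and against more splitting of regions, since a shared region held 1.06 peaks in replicate 2 and 1.13 in replicate 1. The control was shallower in replicate 2, but among summits of at least 6.45 times the ChIP depth, high enough to be called in both replicates with control up to 2 times the background, replicate 2 had 1.81 times as many peaks (exact binomial interval 1.76 to 1.85), and 1.52 to 2.00 times at the 10 higher levels tried (9 and 18 peaks at the highest), which goes against control depth for these. Weaker summits held little of the surplus at that level, with 12961 peaks in replicate 1 and 13400 in replicate 2 (1.03 times), although the split moves with whole reads and 6.5 times the depth left 9745 and 16213 peaks above it; for them control depth stays open, as the smallest summit called at the background was higher in replicate 2, 3.65 against 3.20 times the depth, but a smaller share of its peaks had control above the background. The depth-normalised summits at shared regions were 1.25 times as high in replicate 2, so a higher yield of the immunoprecipitation is a candidate explanation, but an equal rise at every site is not seen at the 10 best-ranked regions, with ratios of 0.90 to 1.07 and a median of 1.04.

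The X chromosome had 0.27 times the autosomal density of shared regions; one X copy per cell would halve the reads at X sites, and the control is consistent with it, since 6.11% of X peaks in replicate 2 had control coverage above the background against 41.9% of autosomal peaks. Autosomal regions that would pass the smallest called read number after halving had a density of 3.86 per Mb, or 2.44 with the 5th percentile in its place. Both were above the X bound of 2.19. The densities at 11 and 22 reads (X 1.96, autosomes 4.09) and at 15 and 30 reads (X 1.81, 1.60 to 2.03, autosomes 2.17) also differed by more than counting error. The bound and intervals leave out differences between chromosomes, and single autosomes ran from 5.31 to 12.02 shared regions per Mb. These comparisons thus cannot decide whether the copy number is the whole cause. Regions with few reads are only partly detected, which affects these comparisons: autosomal density was 7.31 per Mb with at least 11 reads, 6.95 with at least 15 and 4.86 with at least 20. X regions with at least 20 reads in both replicates had 1.13 per Mb (0.97 to 1.31) and autosomal regions with at least 40 reads 1.104, and at 25 and 50 reads the values were 0.58 (0.46 to 0.71) and 0.64, at 30 and 60 reads 0.39 (0.30 to 0.50) and 0.39. One copy thus remains a candidate explanation from 20 reads upward, a limit picked after seeing the values, and what lowers the number of weaker sites stays open, with differences in gene content and in sequence that can be aligned.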

How the results depend on the processing

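Leaving out peaks with high control coverage, ranking by fold and the alternatives for the X chromosome were added after seeing the data. Taking the 50% of each list with the higher score left 11353 and 15501 peaks by construction, and these formed 9869 shared regions; the share of replicate 1 peaks with a partner was then 90.7% and the Spearman correlation of the scores 0.81. That share was 81.5% with the longer list trimmed to the length of the shorter, 59.5% under 50% reciprocal overlap and 87.9% without peaks whose control coverage was over 2 times the background. The Spearman correlation was 0.84 under reciprocal overlap, 0.80 without the high-control peaks and 0.74 for fold enrichment. The excess over random placement, the short gaps and the low X density kept their direction and side of the threshold under every alternative run. The Monte Carlo chi-square p for chromosome shares stayed at 0.9872 to 0.9998. These p-values compare lists that share most of their peaks, which lowers the statistic, so they say little about robustness. With 1 replicate left out, the gap ratio was 0.26 to 0.30 and the X ratio 0.25. Leaving out a replicate gives no value for the overlap or the agreement, and the placement excess was not computed for reciprocal overlap. The alternatives for promoters, gene lists and sequence were not run, for want of an annotation and sequence of the build. No paired analysis was possible because the inputs sharing replicate numbers with the ChIP samples have no values of their own here. Depth limits the weak end: the lowest quintiles rested on medians of 15 and 17 reads per summit.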

Other observations

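Stronger CHD8 regions were wider. The median width of shared regions was 541 bp in the weakest quintile by rank and 1588 bp in the strongest, with median fold enrichments of 3.38 and 9.91 in replicate 1 and 4.18 and 11.4 in replicate 2. Called width grows with signal at a fixed threshold, so width and strength are not separate measures. The widest shared region was on chromosome 17 at 34254135 to 34260379, 6.25 kb, with fold enrichments of 15.2 and 18.4; replicate 1 held it as 2 peaks and replicate 2 as 1. The region on chromosome 8 at 87183762 to 87189707 followed with 5.95 kb, inside a window that was also among the densest. The region on chromosome 18 at 75406965 to 75412419, 5.46 kb, held 4 peaks in replicate 1 and 1 in replicate 2, with folds of 4.27 and 7.73.

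The densest window lies on chromosome 13, which also carries the large mouse cluster of replication-dependent histone genes. The 64 regions were not assigned to genes here, and whether they fall in that cluster was not tested.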
